A study of Mus musculus with 6 samples.

How the data were processed

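The samples were 6 samples of liver tissue from mice on the same diet, 3 per group, with RNA extracted in TRIzol and 500 ng used for stranded, poly(A)-selected libraries, per the labels' protocols. Per the submitters' processing notes, Trimmomatic 0.36, HISAT2 2.2.1.0 and HTSeq 0.9.1 were used with the mouse build GRCm39; the annotation, the strand setting of the counter and any filter are not given in the sources used here. The deposited values are raw counts, whole reads per gene symbol with no normalization, in 1 table with 1 column per sample; this unit was read from the values and the table's own name. All 6 columns were used. The table held 17119 symbols, of which 442 had no count in any library, and 0 rows without a gene name. Of the symbols, 16573 matched a table of mouse gene names, and 17023 matched a RefSeq table of the older build GRCm38.p6, so no coordinates are given. No mitochondrially encoded symbol was among them. Genes with close copies (Saa1 and Saa2, the Orm, Mup, Acot and Cyp2c genes, Lyz1 and Lyz2, Ms4a6c and Ms4a6d, the Fcgr genes, Hba-a1 and Hba-a2) are uncertain, since reads may have been split or dropped between copies, and so are genes with an overlapping antisense partner.

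Groups and replicate numbers were taken from the sample titles. The genotype labels of replicates 2 and 3 name the Cre driver with a number that counts up with the replicate, whereas the series design names Clec4f for all animals, and the design was followed. The labels name no batch, sex or litter per sample. They do not tie each sample to an animal of its own, so p-values measure the spread between these samples. Library totals ran from 16895322 to 17750755, and TMM factors from 0.924 to 1.041. The most abundant gene, Alb, took 6.89% to 9.30% of counts and the top 10 genes 17.9% to 20.8%. No 2 libraries agreed within sampling noise: the chi-square per degree of freedom between pairs lay between 22.2 and 107.8. Deviations from the group means correlated at −0.21, −0.31 and 0.19 between same-numbered libraries, so the numbers were not treated as pairs.

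In R 4.3.3, genes were filtered with edgeR 4.0.16 (filterByExpr by group), scaled by TMM and tested with glmQLFit and glmQLFTest (robust), without covariates, and p-values were adjusted by Benjamini-Hochberg at 0.05. SEs are the absolute log2 fold change divided by the square root of F, and 95% intervals use the t distribution at the test's degrees of freedom. CPM values are TMM-scaled; log2 CPM for lists used a prior count of 2. Gene lists with at least 3 tested members were compared with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 33 lists; camera compares a list with all other genes. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were alternatives. Alternatives for genes were edgeR's RLE and upper-quartile scaling, no filter on low counts, at least 1 CPM in 3 samples, DESeq2 1.42.0, limma-voom, the replicate number as a block, haemoglobin genes left out, a non-robust fit, other thresholds, and each library left out in turn. The comparison, tests, lists, named-gene rule and these alternatives were fixed before the data were examined. Leaving out 2 libraries together and an acute phase covariate were added after seeing the data. The covariate is the mean log2 CPM of the acute phase list, which camera at the preset correlation itself called lower in the heterozygous livers. It may take out part of the group difference, so calls lost or gained with it have no single reading.

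Named genes were Cebpb and Clec4f, then up to 12 rises and 12 falls with the largest fold change among genes past the threshold with a mean log2 CPM of at least 0 and no overlap between groups, and for each list described up to 4 members with the smallest p plus those past the threshold. Bst1, with the next largest fall after Nos2 but a mean log2 CPM of −0.01, was left out by this rule. The 34 lists were Kupffer cell identity, lipid-associated macrophages, monocytes and recruited macrophages, alternative activation, neutrophils, T and NK cells, B and plasma cells, dendritic cells, MHC class II antigen presentation, liver sinusoidal endothelium, stellate cells and fibrosis, cholangiocytes, inflammatory cytokines, interferon-stimulated genes, acute phase proteins, de novo lipogenesis, cholesterol synthesis, fatty acid oxidation, lipid droplets, bile acid synthesis, xenobiotic metabolism, glucose metabolism, oxidative phosphorylation, ER stress, cell cycle, the C/EBP family, immediate early genes, circadian clock, male-biased and female-biased liver genes, red blood cells, exocrine pancreas, adipose tissue and sex chromosome genes. Lists shared no genes except Fabp4 and Cfd (lipid droplets and adipose tissue) and Cyp7b1 (bile acid and male-biased).

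The test was run on simulated counts for this comparison, with 12706 genes of which 200 were changed, and with the 14 tested genes of the lipid-associated macrophage list lowered 2-fold besides. It recovered 5 of 67 genes changed 1.5-fold, 42 of 67 changed 2-fold and 62 of 66 changed 4-fold, so changes under 2-fold were mostly beyond reach at this depth and number of libraries. It also called 7 of the 14 list genes. Of its 129 calls 13 were false, a larger share than the nominal 5%; DESeq2 made 34 false calls and limma-voom 13. The list shifted on purpose was called together with 1 list that was not shifted. With no gene changed, 1 gene and 0 lists were called. In the real libraries the estimated correlation between genes of a list ran from −0.114 (cholangiocytes) to 0.869 (MHC class II). Simulated counts that do not carry these correlations cannot show how often camera with a preset correlation calls lists falsely. The simulated list calls are therefore not read as a check on the list calls below.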

Results

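RNA was sequenced from 6 samples of unfractionated liver tissue of mice that had been kept for 12 weeks on a diet high in fat and cholesterol, which is used to bring on steatohepatitis, a fatty liver with inflammation. All animals carried iCre under the Clec4f promoter, which is active in Kupffer cells, the resident macrophages of the liver. In 3 samples 1 Cebpb allele was floxed, so that Kupffer cells lost 1 copy of the gene (called heterozygous livers here), and the 3 wild-type samples came from littermates with both copies intact (wild-type livers). Cebpb encodes C/EBPβ, a transcription factor of macrophages and hepatocytes. The wild-type libraries held 17750755, 17665622 and 17673848 counts and the heterozygous libraries 17149924, 16895322 and 17008597, so every wild-type library was slightly deeper. Of 17119 gene symbols, 12706 passed the filter on low counts and were tested. Levels are given in CPM, read counts scaled by library size and TMM factor, with the SD over 3 libraries, and log2 fold changes are heterozygous over wild-type with their SE.

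The targeted gene was examined first. Cebpb RNA stood at 506, 308 and 340.4 CPM in wild-type replicates 1, 2 and 3 and at 204, 498 and 269 CPM in the heterozygous replicates. The means of 385 ± 106 and 324 ± 154 CPM differed by less than the spread between libraries (log2 fold change −0.25 ± 0.37, 95% interval −1.13 to 0.64, edgeR adjusted p = 0.864). Whole liver also holds Cebpb RNA of cells without the deletion, so this level checks the labels only weakly, and directions below are those of the labelled groups. Clec4f, a lectin gene specific to Kupffer cells, measured 48.6 and 38.5 CPM in wild-type replicates 1 and 2 but 5.42 CPM in wild-type replicate 3. The heterozygous libraries lay at 4.31, 4.97 and 3.90 CPM. The log2 fold change of −2.81 ± 0.85 did not pass the threshold (edgeR adjusted p = 0.260), but the gene passed without wild-type replicate 3 (−3.31, edgeR adjusted p = 0.000607) and in DESeq2 (−2.80, adjusted p = 0.0215). Over all alternatives the adjusted p of Clec4f from edgeR, DESeq2 and limma ran from 0.000607 to 0.662. The number of iCre copies, which could alter the Clec4f locus, is not in the labels. The Clec4f difference between the groups may therefore not reflect Kupffer cells alone.

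**Figure D1:**
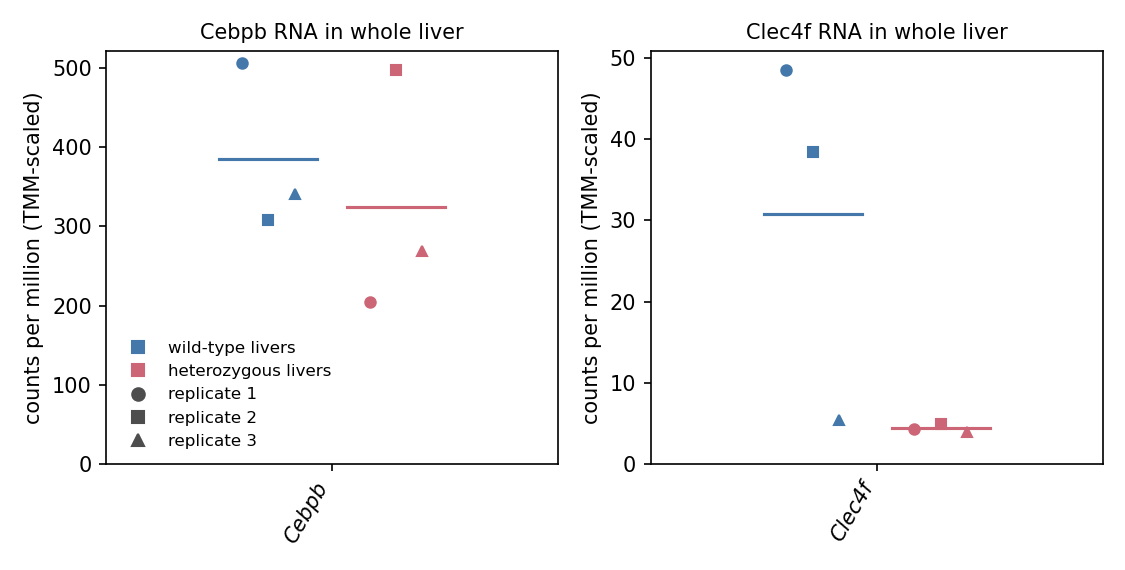
Cebpb (left) and Clec4f (right) RNA in each whole-liver library, in TMM-scaled CPM. Points are libraries, with the marker shape giving the replicate number, and horizontal lines are group means. Cebpb overlaps between the groups, and wild-type replicate 3 lies at 5.42 CPM for Clec4f, next to the heterozygous libraries.

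The comparison of the 2 groups asks which liver genes respond to the loss of 1 Kupffer cell copy of Cebpb on this diet. Genes known from macrophages and other leukocytes were among the largest falls, and 10 of the 74 genes past the threshold belong to a gene list fixed beforehand. Nos2, the inducible nitric oxide synthase of activated macrophages, fell 8.57-fold, from 5.07 ± 1.29 to 0.582 ± 0.311 CPM (log2 fold change −3.10 ± 0.39, edgeR adjusted p = 0.0308). Slamf8, a receptor of activated myeloid cells, fell 4.73-fold (−2.24 ± 0.37), and Clec4e, the Mincle receptor for dead cells and microbial glycolipids, fell 4.58-fold (−2.20 ± 0.33). Pla2g7, the secreted platelet-activating factor acetylhydrolase of macrophages, fell 4.04-fold, from 22.4 ± 2.45 to 5.54 ± 1.51 CPM. Lyz2, the lysozyme of myeloid cells, fell 3.20-fold, from 262 ± 81.2 to 81.9 ± 11.6 CPM, and Il2rg, the shared chain of several interleukin receptors, fell 3.21-fold. The other genes among the 12 largest falls were Dram1, Parvg, Ms4a6c, Adap1, Cyp4f18 and Sema4d, with falls between 3.35-fold and 4.25-fold. Further genes that fell, picked from the calls after their values were seen, were the leukocyte adhesion genes Vcam1 (log2 fold change −1.68 ± 0.20) and Itgb2 (−1.58 ± 0.19), the NADPH oxidase subunits Cyba (−1.45 ± 0.15) and Ncf1 (−1.53 ± 0.24), the Fc receptors Fcgr1, Fcgr3 and Fcgr4, the complement genes C1qa and C1qb, the myeloid transcription factor gene Spi1 (−1.30 ± 0.21) and the haem oxygenase gene Hmox1 (−1.33 ± 0.18).

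At this threshold 3 genes rose in edgeR, against 82 in DESeq2, 21 with no filter on low counts, 31 with the acute phase covariate, 1 in limma-voom (Sned1) and 0 with a non-robust fit. Sned1, which encodes an extracellular matrix protein, rose 2.05-fold, from 6.04 ± 0.61 to 12.4 ± 0.57 CPM. Tubb2a, a β-tubulin gene, rose 2.0-fold (78.5 ± 12.7 to 157 ± 29.3 CPM). Abhd6, a monoacylglycerol lipase gene, rose 1.55-fold (43.2 ± 3.89 to 67.0 ± 3.62 CPM). Their edgeR adjusted p-values were 0.0357, 0.0494 and 0.0494.

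In all, 74 of 12706 genes passed an edgeR adjusted p of 0.05, 71 lower and 3 higher in the heterozygous livers. The adjusted p-values lay between 0.0308 and 0.0494. For each of the 74 the libraries of the groups did not overlap, as was the case for 2334 of all tested genes (18.4%, against 10% by chance). Of the lower genes, 69 fell at least 2-fold, and the median fall was 2.54-fold. The number of calls depended on single libraries. Without wild-type replicate 1, 2 or 3 edgeR called 4, 6 and 20 genes. Without heterozygous replicate 1, 2 or 3 it called 0, 0 and 122. Of the 74 genes, 0 were called in all of these fits. All 74 kept their sign in each, which the lack of overlap between their groups all but fixed beforehand. For the fits with 0 calls, 1104 and 1601 genes had an unadjusted p under 0.05, and with all libraries DESeq2 called 534 genes (452 lower and 82 higher), among them the 74, limma-voom 46 (45 lower and 1 higher), and 1143 lower and 534 higher genes had an unadjusted edgeR p under 0.05.

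**Figure D2:**
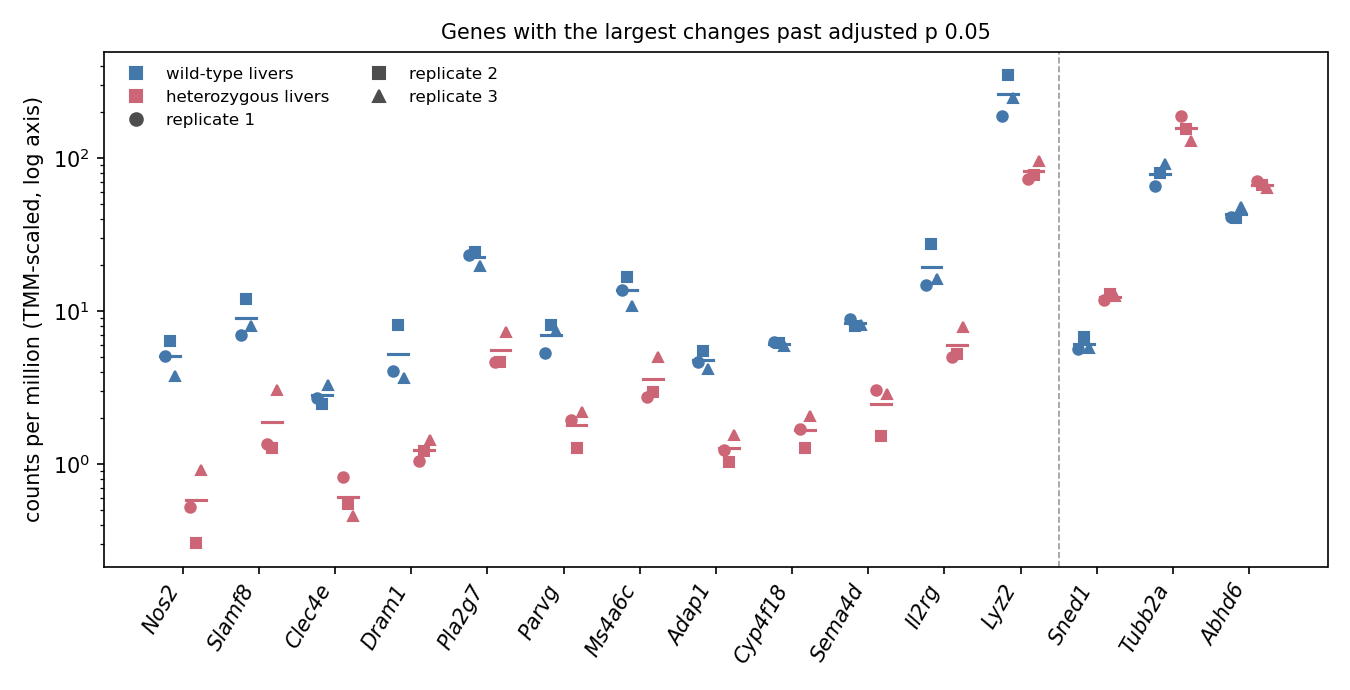
Levels of the 12 genes with the largest falls (left of the dashed line) and the 3 genes that rose (right) in each library, in TMM-scaled CPM on a log axis. Points are libraries, with the marker shape giving the replicate number, and horizontal lines are group means. In each gene the 3 heterozygous libraries lie on one side of the 3 wild-type libraries, as for Nos2 with means of 5.07 and 0.582 CPM.

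Gene lists fixed before the data were examined were then compared as groups with limma camera at a preset correlation of 0.01. Of 33 lists tested, 12 were lower and 3 higher in the heterozygous livers. None of the 15 calls held when the correlation between genes was estimated from these libraries. Camera then also uses the few degrees of freedom left by 6 libraries, so this loss does not come from correlation alone. The alternative activation list had an estimated correlation of −0.047, below the preset 0.01. Its camera adjusted p still went from 0.0287 to 0.278. The fry test called 5 lists, all lower, and its adjusted p-values for these are given below. For the remaining lists called by camera, fry adjusted p ran from 0.054 (interferon-stimulated genes) to 0.505 (sinusoidal endothelium). It was 0.0777 for both MHC class II and dendritic cell genes and 0.123 for both Kupffer cell identity and stellate cell genes.

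Monocyte and recruited macrophage genes were lower as a group, with a median log2 fold change of −1.29 over 13 genes (camera adjusted p = 4.78e-11; adjusted p = 0.182 with an estimated correlation; fry adjusted p = 0.0246). Ccr2, the receptor that draws monocytes into tissue, fell 3.0-fold from 6.30 ± 0.40 to 2.09 ± 0.20 CPM, and Lyz2 is the other member past the threshold over all genes. Adjusted over the list alone, 11 of the 13 were lower. Plac8 measured 17.5 ± 5.48 CPM in wild-type and 7.96 ± 1.34 CPM in heterozygous livers. Lipid-associated macrophage genes, which mark macrophages around fat-laden cells, had a median of −0.83 over 14 genes (camera adjusted p = 6.46e-08; adjusted p = 0.182 with an estimated correlation; fry adjusted p = 0.0246). Lgals3 fell 2.38-fold and Cd68, a lysosomal macrophage marker, 2.05-fold, and 8 of the 14 were lower when adjusted over the list alone. Members that did not pass over the list alone, given here after their values were seen, were Trem2 (log2 fold change −0.72 ± 0.53), Cd9 (−0.06 ± 0.19), Mmp12 (−0.90 ± 0.46), Lpl (−0.46 ± 0.24), Ctsd (−0.25 ± 0.13) and Ctsb (−0.22 ± 0.11). Gpnmb stood at 20.6 ± 6.48 and 5.19 ± 2.73 CPM and Fabp5 at 25.9 ± 8.41 and 10.3 ± 2.29 CPM, with edgeR adjusted p-values of 0.132 and 0.0602.

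Kupffer cell identity genes had a median of −0.58 over 13 genes, 11 with a negative and 2 with a positive fold change (camera adjusted p = 0.000137; adjusted p = 0.416 with an estimated correlation). Without wild-type replicate 1 and heterozygous replicate 2 together the median was −0.87 (camera adjusted p = 0.000455). Il18bp, which encodes a binding protein of interleukin 18, fell 2.35-fold from 46.8 ± 10.1 to 19.9 ± 1.58 CPM and was the member past the threshold over all genes, against 7 adjusted over the list alone. The scavenger receptor gene Marco measured 15.6 ± 13.8 CPM in wild-type and 1.97 ± 0.80 CPM in heterozygous livers, Cd5l 181 ± 68.4 and 77.5 ± 13.9 CPM, and Spic, which encodes a transcription factor of iron-handling macrophages, 4.01 ± 2.51 and 0.753 ± 0.569 CPM. None of these 3 passed over all genes (edgeR adjusted p = 0.176, 0.103 and 0.152). Members that did not pass over the list alone, given here after their values were seen, were Folr2 (log2 fold change 0.41 ± 0.42), C6 (0.10 ± 0.25), Nr1h3 (−0.03 ± 0.12), Slc40a1 (−0.23 ± 0.17), Id3 (−0.25 ± 0.15) and Timd4 (−0.49 ± 0.38). The alternative activation list had 5 tested genes, a median of −0.30 and a camera adjusted p of 0.0287 (adjusted p = 0.278 with an estimated correlation; fry adjusted p = 0.0453). Its call came with Clec10a at 1.5 ± 0.17 and 0.410 ± 0.151 CPM, the member past the threshold over the list alone, while Arg1, which hepatocytes also express strongly, differed by 1.24-fold with overlapping libraries. This call was lost without wild-type replicate 1 (median −0.13, camera adjusted p = 0.121) or heterozygous replicate 3 (0.146), with no filter on low counts (0.147) and with the acute phase score as a covariate (median −0.10, adjusted p = 0.476).

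Other leukocyte groups were lower too. All 8 tested genes of MHC class II antigen presentation were lower when adjusted over the list alone and 0 over all genes, with a median of −1.59 (camera adjusted p = 6.46e-08; adjusted p = 0.308 with an estimated correlation). Cd74, the invariant chain, measured 1425 ± 662 and 346 ± 179 CPM, and H2-Ab1 388 ± 94.4 and 129 ± 52.7 CPM. Dendritic cell genes had a median of −1.27 over 10 genes, 6 of them lower over the list alone and 0 over all genes (camera adjusted p = 4.30e-06; adjusted p = 0.278 with an estimated correlation). Xcr1 and Clec9a, markers of cross-presenting dendritic cells, measured 2.23 ± 0.96 and 8.98 ± 0.205 CPM in wild-type livers and 0.697 ± 0.446 and 4.88 ± 1.79 CPM in heterozygous livers. Neutrophil genes had a median of −1.48 over 6 genes (camera adjusted p = 0.000283; adjusted p = 0.182 with an estimated correlation; fry adjusted p = 0.0453), with Csf3r, the receptor of granulocyte colony-stimulating factor, past the threshold over all genes at 2.38-fold lower and 3 members over the list alone. With the acute phase score as a covariate the neutrophil median was −0.81 (camera adjusted p = 0.0252). Lcn2 in this list is also made by hepatocytes in the acute phase and varied widely, with 206 ± 253 and 29.5 ± 19.7 CPM. Lcn2, Mmp9 (log2 fold change −0.69 ± 0.47) and Cxcr2 (−0.49 ± 0.57) did not pass over the list alone. Of the 12 listed neutrophil genes 6 were tested, and Ly6g, Retnlg, Camp, Ngp, Mmp8 and Il1r2 did not pass the filter on low counts. T and NK cell genes had a median of −0.71 over 12 genes, 3 lower over the list alone and 0 over all genes (camera adjusted p = 0.000109; adjusted p = 0.278 with an estimated correlation), and Cd3g measured 3.21 ± 1.36 and 1.37 ± 0.15 CPM.

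Inflammatory cytokine and chemokine genes had a median of −0.95 over 16 genes (camera adjusted p = 2.72e-07; adjusted p = 0.182 with an estimated correlation; fry adjusted p = 0.0246). Besides Nos2, the chemokine gene Ccl5 fell 2.54-fold from 19.0 ± 2.22 to 7.45 ± 1.52 CPM, and 6 of the 16 were lower when adjusted over the list alone. Interferon-stimulated genes had a median of −0.48 over 14 genes (camera adjusted p = 4.30e-06; adjusted p = 0.278 with an estimated correlation). Zbp1, a sensor of Z-form nucleic acids, fell 2.55-fold and Oasl2 2.08-fold, and 5 of the 14 were lower over the list alone. Acute phase protein genes, which hepatocytes express in inflammation, had a median of −0.68 over 18 genes, with 0 past the threshold over all genes or over the list alone (camera adjusted p = 0.000123; adjusted p = 0.650 with an estimated correlation). The mean log2 CPM of this list stood apart in wild-type replicate 1, at 10.55, against 9.06 and 9.44 in wild-type replicates 2 and 3 and 8.57, 9.28 and 8.68 in the heterozygous replicates, so the groups overlapped. Without wild-type replicate 1 the list median was −0.16 (camera adjusted p = 0.0311), and without that library and heterozygous replicate 2 together it was −0.42 (6.41e-06). Hp, the haptoglobin gene, measured 6480.1 ± 2766 and 4052 ± 713 CPM.

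Stellate cell and fibrosis genes had a median of −0.80 over 21 genes, with 9 lower when adjusted over the list alone and 0 over all genes (camera adjusted p = 2.46e-06; adjusted p = 0.416 with an estimated correlation). Mmp2, a gelatinase gene, measured 12.7 ± 3.67 and 5.87 ± 1.23 CPM, the basement membrane collagen gene Col4a1 73.2 ± 9.66 and 42.0 ± 10.4 CPM, and Timp1, an inhibitor of metalloproteinases, 2.37 ± 0.79 and 0.464 ± 0.444 CPM. Of the 21 members, 18 had a negative and 3 a positive fold change. The 3 positive ones were Acta2 (log2 fold change 1.03 ± 0.44), Lrat (0.14 ± 0.13) and Tagln (0.05 ± 0.18). Among further genes of the list that are not matrix genes, Des (−0.01 ± 0.18) was flat and Pdgfrb (−0.59 ± 0.19) was negative. These members were picked after their values were seen. Liver sinusoidal endothelial genes went the other way, with a median of 0.27 over 13 genes, 3 of them higher over the list alone and 0 over all genes (camera adjusted p = 0.0287; adjusted p = 0.691 with an estimated correlation). Bmp2, a signal from endothelium to hepatocytes in iron control, measured 7.31 ± 1.49 CPM in wild-type and 15.3 ± 3.82 CPM in heterozygous livers (edgeR adjusted p = 0.0639). The endothelial call was lost without wild-type replicate 1 (median 0.16, camera adjusted p = 0.108), wild-type replicate 2 (median 0.29, adjusted p = 0.0936) or heterozygous replicate 2 (median 0.09, adjusted p = 0.292), and without wild-type replicate 1 and heterozygous replicate 2 together (median 5.24e-05, adjusted p = 0.552).

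Among hepatocyte functions, 2 lists were higher as groups by small amounts. Fatty acid oxidation genes and targets of PPARA had a median of 0.17 over 22 genes, of which 17 had a positive fold change and 0 passed over all genes or over the list alone (camera adjusted p = 0.00437; adjusted p = 0.541 with an estimated correlation). Acot1, an acyl-CoA thioesterase gene, measured 24.0 ± 8.48 and 43.3 ± 4.12 CPM. Genes of bile acid synthesis and sterol transport had a median of 0.21 over 17 genes, with 2 higher over the list alone and 0 over all genes (camera adjusted p = 0.0116; adjusted p = 0.464 with an estimated correlation). Abcg5 and Abcg8, whose products export sterols into bile, measured 268 ± 17.9 and 320.2 ± 48.4 CPM in wild-type livers and 383 ± 23.4 and 433 ± 32.7 CPM in heterozygous livers. The bile acid call was lost without heterozygous replicate 1 (median 0.13, camera adjusted p = 0.0525), and its median was 0.14 without wild-type replicate 1 (adjusted p = 0.0463). Both calls were lost with the acute phase score as a covariate, with medians of 0.10 (camera adjusted p = 0.114) for fatty acid oxidation and 0.10 (0.247) for bile acids. That score is partly tied to the groups, so this loss does not show that the acute phase response drives these rises.

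**Figure D3:**
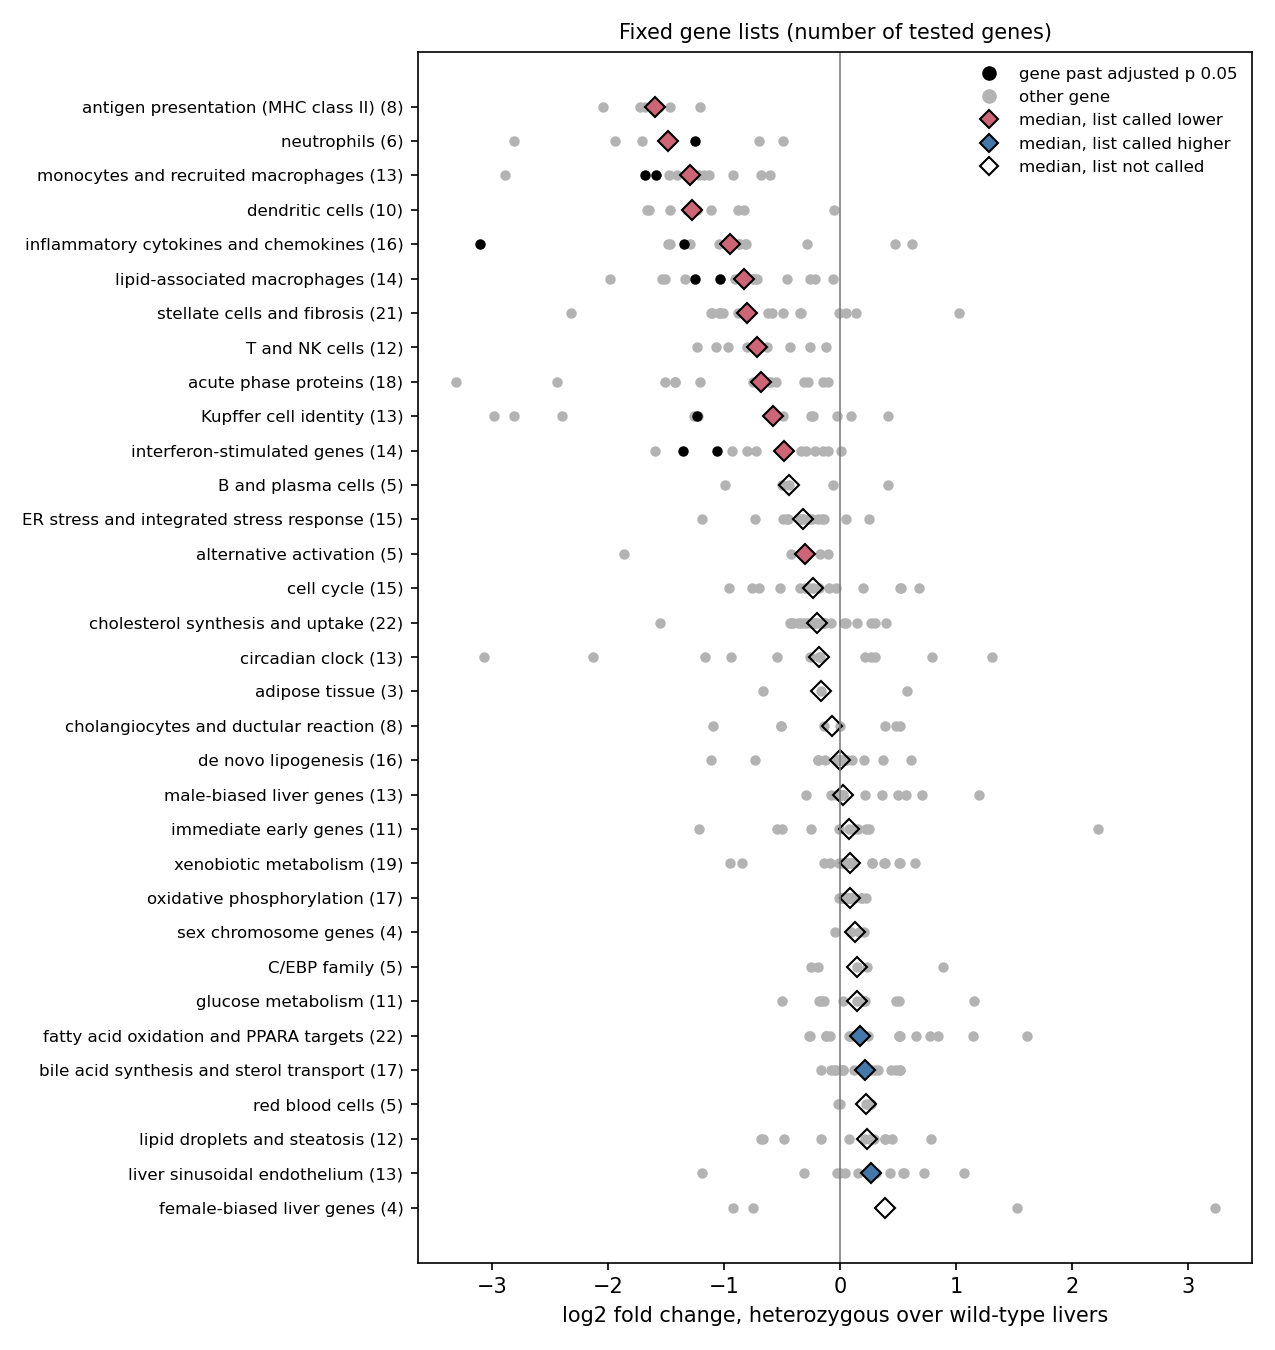
Log2 fold change (heterozygous over wild-type livers) of each tested gene in the 33 lists, with the number of tested genes in brackets. Black points are genes past an edgeR adjusted p of 0.05, grey points are other genes, and diamonds are list medians, filled where camera with a preset correlation called the list. The MHC class II list lies lowest at −1.59, and the sinusoidal endothelial list lies at 0.27.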

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

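The acute phase covariate and the removal of 2 libraries together were chosen after seeing the data. The 74 calls became 37 with upper-quartile scaling, 48 with at least 1 CPM in 3 samples, 46 with limma-voom and 20 with a non-robust fit, and 211 with no filter on low counts (21 higher, 190 lower), 534 with DESeq2 (82 higher, 452 lower) and 298 with the acute phase covariate (31 higher, 267 lower). Other thresholds gave 325 (adjusted p below 0.1; 33 higher, 292 lower), 568 (unadjusted p below 0.05 and at least 2-fold; 40 higher, 528 lower) and 1677 genes (unadjusted p below 0.05; 534 higher, 1143 lower). RLE scaling (50) and leaving out haemoglobin genes (74) stayed within 1.5 times. Leaving out 1 library gave 0 to 122 calls, and leaving out wild-type replicate 1 and heterozygous replicate 2 together gave 4, of which 1 was among the 74. The replicate block left 0 calls in edgeR (1427 genes at an unadjusted p below 0.05; no other tool was run with it); same-numbered libraries did not deviate together, so this loss is not read as a weaker effect. The sign of all 74 was the same in every fit. Their groups did not overlap, so for fits without 1 library this was nearly fixed beforehand and adds no support. Of the 74, 0 were called in every fit without 1 library. The main adjusted p-values of the 74 lay between 0.0308 and 0.0494. Cebpb moved between −0.70 and 0.016 when 1 library was left out and to 0.33 with the covariate. Clec4f ranged from −3.31 to −2.30 without 1 library, passing without wild-type replicate 3, and passed in DESeq2 at −2.80. Of 33 lists, 15 were called, 15 to 17 without 1 library and 16 with the block, 0 with an estimated correlation (4 at an unadjusted p below 0.05; 5 by fry); 12 of the 15 were called in every fit without 1 library, the exceptions being alternative activation, sinusoidal endothelium and bile acid synthesis. Lists gained under 1 setting or another were oxidative phosphorylation, ER stress (also with the block, camera adjusted p = 0.0471), cholesterol synthesis, xenobiotic metabolism, cell cycle, male-biased genes and B and plasma cells. With the covariate the lipid droplet list turned from a median of 0.24 to −0.44 and passed as lower (camera adjusted p = 0.0252), and the immediate early list, with a positive median before (0.08) but a camera direction of lower, passed as higher at 0.69 (0.0268). The cause of these changes was not tested.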

Other observations

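The tests of endothelial genes, of Kupffer cell genes and the label in wild-type replicate 3, and of Cebpb against acute phase genes were chosen after the results were seen. The splits, the thinning and the immediate early genes were not, although the 2 libraries of the immediate early test were named from their Cebpb and acute phase levels.

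With all libraries, lipid-making and sterol genes did not pass as groups, although single members lay apart. De novo lipogenesis had a median log2 fold change of 0.00 and a mean of −0.06 over 16 genes (camera adjusted p = 0.804), with Thrsp at 299.5 ± 64.9 CPM in wild-type and 139 ± 38.1 CPM in heterozygous livers and Srebf1 at 419 ± 110.2 and 641 ± 95.2 CPM. In the lipid droplet list (median 0.24, camera adjusted p = 0.767) the lipase gene Pnpla2 measured 154 ± 10.5 and 96.1 ± 13.7 CPM (edgeR adjusted p = 0.0539). Cholesterol synthesis (median −0.20, camera adjusted p = 0.0918), xenobiotic metabolism (0.09, 0.295), glucose metabolism (0.15, 0.418), oxidative phosphorylation (0.09, 0.0623) and ER stress genes (−0.32, 0.0702) did not pass either with all libraries. Some passed without 1 library: cholesterol synthesis without wild-type replicate 1 (camera adjusted p = 0.00115) or heterozygous replicate 3 (0.00834), oxidative phosphorylation without wild-type replicate 1 (0.0268) or heterozygous replicate 2 (0.00342), ER stress genes without wild-type replicate 2 (0.00321) or heterozygous replicate 2 (0.0366), and xenobiotic metabolism without heterozygous replicate 2 (0.0280). Oxidative phosphorylation also passed with no filter on low counts (0.0393), cholesterol synthesis with the acute phase covariate (2.57e-05), and both without wild-type replicate 1 and heterozygous replicate 2 together (0.0013 and 0.0368). In the xenobiotic list, Por, which passes electrons to cytochromes P450, measured 512 ± 84.9 and 284 ± 45.8 CPM (edgeR adjusted p = 0.0561).

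Several lists of other cell types and states did not pass with all libraries. These were B and plasma cells (median −0.43, camera adjusted p = 0.429), cholangiocytes (−0.07, 0.767), red blood cells (0.23, 0.429), adipose tissue (−0.16, 0.758), cell cycle (−0.23, 0.311), the C/EBP family (0.14, 0.311), immediate early genes (0.08, 0.753), the circadian clock (−0.18, 0.804), sex chromosome genes (0.13, 0.429), and male-biased (0.03, 0.0918) and female-biased liver genes (0.39, 0.843). Cell cycle genes passed as lower without heterozygous replicate 1 (camera adjusted p = 0.00295) and with the acute phase covariate (0.0368), male-biased genes as higher without heterozygous replicate 3 (0.00249), and B and plasma cell genes as lower with the covariate (median −1.09, 0.0203). The median and the test differed in sign for adipose tissue and immediate early genes, as did mean and median for de novo lipogenesis. Of 12 exocrine pancreas genes 2 were tested, too few for the list test, with Cela1 at 7.73 ± 1.09 and 11.3 ± 2.29 CPM. Cebpe measured 7.13 ± 2.29 and 13.2 ± 2.79 CPM (edgeR adjusted p = 0.159), and the growth hormone target Hsd3b5 83.5 ± 11.3 and 192 ± 59.8 CPM (edgeR adjusted p = 0.0688). The clock gene Ciart stood at 9.15, 17.2 and 1.86 CPM in wild-type replicates 1 to 3 and at 0.291, 1.64 and 1.43 CPM in the heterozygous replicates. The clock list holds genes of opposite phase, so its median decides nothing: Dbp (log2 fold change −2.13 ± 1.12), Per3 (−1.16 ± 0.50) and Nr1d1 (−0.94 ± 0.61) were negative, and Npas2 (1.31 ± 0.56), Cry1 (0.80 ± 0.27) and Arntl (0.30 ± 0.18) positive, with 0 of the 13 past the threshold over the list alone. The Y-linked gene Ddx3y was present in every library, at 29.0 ± 3.70 and 32.5 ± 5.55 CPM.

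Lists of monocyte, macrophage, neutrophil, dendritic, T and NK cell genes were lower in the heterozygous livers with a preset correlation, but no list call held with an estimated one, and B and plasma cell genes did not pass. A smaller share of every non-hepatocyte cell type would lower endothelial genes as well. The sinusoidal endothelial list had a median of 0.2723 (SD of its members 0.552), against −1.292 for monocyte and macrophage genes, which argues against an equal loss of every type. However, Lyve1 (−1.19) and Pecam1 (−0.31) in the endothelial list were negative, and its median was 5.24e-05 without wild-type replicate 1 and heterozygous replicate 2. The stellate cell and fibrosis list had a median of −0.80. It mixes matrix genes with Acta2 (1.03), Lrat (0.14), Tagln (0.05), Des (−0.01) and Pdgfrb (−0.59), so its median leaves the share of stellate cells open. Thinning all libraries to 16895322 counts left the median of the 71 called lower genes at −1.352 (−1.347 before, with 51 calls in place of 74), which decides nothing about depth, since the totals differ by at most 1.05-fold. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many genes (74, the highest other 0), and 10 splits are too few for a share under 0.05. Fewer leukocytes, resident or infiltrating, and lower expression per cell, both possible results of the Cebpb deletion, may each underlie the pattern. Whole-liver counts do not separate them, and litter or time of collection stays open. The number of iCre copies, which the labels do not give for either group, stays open as well.

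Clec4f was 7.83-fold lower in wild-type replicate 3 than in wild-type replicates 1 and 2, a log2 difference of −2.969 with a prior count of 2. A loss of Kupffer cells as large as that of Clec4f is argued against by the 12 other Kupffer cell genes, with a median difference of −0.4562 (SD 0.510). Marco (−1.65) and Folr2 (−1.41) were also far lower. All of the 12 except Slc40a1 (0.03) were lower, among them Spic (−0.69), Cd5l (−0.49) and Vsig4 (−0.42), with Nr1h3 (−0.09) and Id3 (−0.14) nearest to no change. A smaller loss of Kupffer cells in this library therefore stays open. A heterozygous liver under a wild-type label is argued against by the 19 other genes called without this library, where it took a median position of 0.7393 (quartiles 0.60 and 0.80) from 0 at the heterozygous mean to 1 at the mean of the other wild-type libraries, and lay above all heterozygous libraries in 18. Of the 20 genes called in that fit, Clec4f among them, 1 was higher in the heterozygous livers. The count of 18 takes no account of direction. The bound set for that test was 0.75, which 0.7393 narrowly missed; the reading rests on the lower quartile lying above 0.25, the bound for a wrong label, a criterion adopted after the value was seen. The number of iCre copies, which could alter the Clec4f locus it uses, is not in the labels and was not tested, and neither was a biological cause.

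Cebpb and the acute phase list were each highest within their group in wild-type replicate 1 and heterozygous replicate 2, which also stood apart on the second principal component (28.6% of variance), with Mt1 at 1577 and 346 CPM against 7.92 to 82.7 CPM elsewhere, a gene chosen after its values were seen. The immediate early list had its 2 highest scores, 4.90 and 4.55, in these 2 libraries (2 of 2, where 1 of 15 pairs would do so by chance), against 3.82 to 3.99 elsewhere. A response to collection or handling may contribute. The scores cannot tell it from another response in these livers that raises immediate early and acute phase genes together. Cebpb set against the acute phase list across the 6 libraries gave Pearson r = 0.8116 (exact permutation p = 0.0333, adjusted 0.10 over 3 relations) and Spearman rho = 0.943 (exact permutation p = 0.0167, adjusted 0.050). Without the 2 libraries farthest from the median score of the list, r was 0.649. The libraries left out there were wild-type replicate 1 and heterozygous replicate 1, so heterozygous replicate 2 stayed in. After adjustment r does not pass, so 6 libraries leave open whether whole-liver Cebpb RNA follows the acute phase response, although both measures put the 3 libraries of each group in the same order. The 3 relations included Cebpb against the Kupffer cell list (r = 0.266, exact permutation p = 0.613) and the monocyte list (r = 0.174, exact permutation p = 0.722). For these lists the groups lay apart, so r mixes the group difference with any relation inside the groups, and it decides nothing about the latter. Wild-type replicate 1 and heterozygous replicate 2 lie in different groups, and no biological explanation from the design was tested.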
